A study of Mus musculus with 14 samples.

How the data were processed

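The series describes 14 mouse samples: 4 poly(A) RNA-seq libraries, 8 ChIP-seq libraries for 4 histone marks (H3K4me3, H3K4me1, H3K27me3 and H3K27ac) and 2 input DNA libraries. The processed table used here holds the 4 RNA libraries, and the 10 ChIP and input samples were not analysed here. Each group therefore has 1 library. Groups were taken from the sample titles, and each column of the table was matched to a sample by its title.

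The deposited table gives log2 values per gene and library, which its name describes as FPKM (fragments per unit of transcript length and of sequencing depth) and as normalised. For 99.7% of the non-zero values, 2 to the power of the value minus 1 gave a number with at most 6 significant digits, the form in which a program writes FPKM. The same test without the subtraction gave 86.7%, and the natural and decimal exponentials gave 0%. Values of exactly 0 and the lowest steps fit log2(FPKM + 1), which was used. The submitters' processing notes list CASAVA 1.8, TopHat2 2.0.9, HTSeq, DESeq2, Bowtie 0.12.8 and the mouse build mm10, with no role or order. The program that gave the FPKM values, and any further scaling between libraries, are not given in the sources used here. Libraries were made with a poly(A) selection kit, per the labels' protocols, which do not say whether reads keep their strand. Reads of overlapping, antisense and near-identical genes may therefore be split or joined, and some rows carry the merged symbols of overlapping genes.

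The table has 13199 rows, and in each at least 1 library exceeds 1 FPKM, so genes low in all 4 libraries are absent. In 19 rows a spreadsheet had turned the symbol into a date, and these were left out, which leaves 13180 genes. Of the symbols, 12792 (97.1%) matched a RefSeq gene table of assembly GRCm38.p6, the RefSeq form of mm10, from which coordinates were taken. The table of lengths at hand gives gene spans rather than transcript lengths, so no length check was made.

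FPKM values carry no count of reads, and the depth of the libraries is unknown. Among 162 genes under 0.12 FPKM in both, the commonest ratio of Oct4-GFP-ESC to Oct4-GFP-H-ESC was 1.24 (26 genes, and 66 at that ratio times a small whole-number ratio), so that 1 read was worth about 1.24 times more FPKM in Oct4-GFP-ESC. No such step was found for DR-ESC or NPC(GFP-). A value of 0 is reported as listed at 0, and no fold is given against it. Small nucleolar RNA genes had erratic values and are not named.

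Before the data were examined, 5 comparisons were fixed. For each, log2((FPKM + 1) ratio) was computed over genes with at least 1 FPKM in either library, and a gene was counted as higher or lower at a size of at least 2-fold. This scale understates the change of low genes. With 1 library per group there is no test, and counts rest on size alone. The 35 gene lists, also fixed in advance, were scored by the median log2 ratio of their members with at least 1 FPKM in either library. The percentile of this median was taken among 10000 random lists of the same size, drawn from 20 bins of mean log2(FPKM + 1). A list needed 5 members, and stood apart above percentile 99 or below percentile 1. The mitochondrial list had 0 members in the table and the cancer-testis list had fewer than 5, so neither was scored, and the number of lists scored was 32 or 33 per comparison. Some lists share members.

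Genes named in the text follow a rule fixed in advance. It takes the 8 highest and 8 lowest genes of each comparison with at least 5 FPKM in either library, 26 genes fixed by name, and the 4 leading members of each list that stands apart. Not all of these genes are named in the text or drawn. Predicted, uncharacterised and small RNA genes were left out of the ranks, wherever such a symbol occurs in a merged name.

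Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The procedure was tested on simulated data for DR-ESC against Oct4-GFP-ESC, with 11744 genes of which 200 were changed 4-fold. It recovered 100% of these and called 0 unchanged genes, and placed a shifted list at percentile 100. The simulated noise was small against a 4-fold change, the shifted list was drawn from the raised genes, and no abundance trend was simulated. These outcomes follow from that setting, so they check the code and not the accuracy in the real libraries. Of 200 unchanged lists 8 stood apart, above the share of 2% that the percentiles set, so a single list near the limits carries little weight.

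Alternatives fixed in advance were pseudocounts of 0.1 and 5, no FPKM minimum or 5, a 4-fold size, the median ratio of genes with at least 5 FPKM in both libraries set to 0, upper-quartile scaling, equal sums, random lists not matched on expression, the mean in place of the median, and the TGF-beta response list without fibroblast markers. Others were chosen after seeing the data. These were removal of the abundance trend (a running median over 401 genes ordered by mean expression), Oct4-GFP-H-ESC in place of Oct4-GFP-ESC, the 2-cell-like list without gene families and the mesenchymal list without fibroblast markers. Gene families were taken as members of the 2-cell-like list whose symbols begin alike.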

Results

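Poly(A) RNA was sequenced from 4 mouse cell populations, with 1 library for each. Oct4-GFP-ESC are embryonic stem cells that carry a green fluorescent protein reporter of Oct4 (gene Pou5f1), a transcription factor of pluripotent cells. They were grown in serum with the cytokine LIF (10 ng/ml) on mitomycin C-treated fibroblast feeders. Oct4-GFP-H-ESC are the cells of that line sorted for a high reporter signal. The line was also driven towards neural cells, and on day 8 the culture was sorted on the reporter. Its GFP-negative cells are the neural progenitors, NPC(GFP-), and its GFP-positive cells, returned to embryonic stem cell medium, are the differentiation-resistant cells, DR-ESC. The series also holds 8 histone mark ChIP-seq samples and 2 input samples, which were not analysed here.

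FPKM values of 13180 genes were used. The sum of FPKM was 687303 in Oct4-GFP-ESC, 437605 in Oct4-GFP-H-ESC, 398522 in DR-ESC and 345804 in NPC(GFP-), and genes of ribosomal proteins took 26.0, 22.1, 22.4 and 15.2% of it. Read depth per library is unknown. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.974 between Oct4-GFP-ESC and Oct4-GFP-H-ESC. DR-ESC had an r of 0.936 with Oct4-GFP-ESC, 0.944 with Oct4-GFP-H-ESC and 0.807 with NPC(GFP-). The r of NPC(GFP-) was 0.760 with Oct4-GFP-ESC and 0.748 with Oct4-GFP-H-ESC. With 1 library per population no difference below has a replicate check, and no p-value or standard error is given. A gene counts as higher or lower when log2((FPKM + 1) ratio) is at least 1 or at most -1. A gene list stands apart when its median log2 ratio lies above percentile 99 or below percentile 1 of 10000 random lists matched on expression, which describes these libraries alone. Comparisons that share a library share its chance values.

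DR-ESC against Oct4-GFP-ESC asks how the cells that kept the reporter through neural differentiation differ from the line they came from. DR-ESC kept the core pluripotency factors at high levels, and had far less RNA of fibroblast genes, less Klf4 and less of the trophoblast, epithelial and LIF response genes. They had more RNA of many formative pluripotency, neural progenitor, sterol synthesis, Hox and 2-cell-like genes, and of some germline genes. Of 12260 genes, 362 were higher and 1492 lower in DR-ESC, with a median log2 ratio of -0.29. The log2 ratio ran with abundance, with a median of -0.997 for the most abundant genes and 0.02 for the least abundant, and the cause of this trend was not tested. With that trend removed, 578 genes were higher and 559 lower. With the median ratio of expressed genes set to 0, 990 were higher and 489 lower (median of all genes 0.11), and with equal sums 2123 and 296 (median 0.41). Against Oct4-GFP-H-ESC, where the median log2 ratio was near 0 (-0.0044), 443 of 12128 genes were higher in DR-ESC and 474 lower, and 489 and 444 with the median ratio set to 0.

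**Figure D1:**
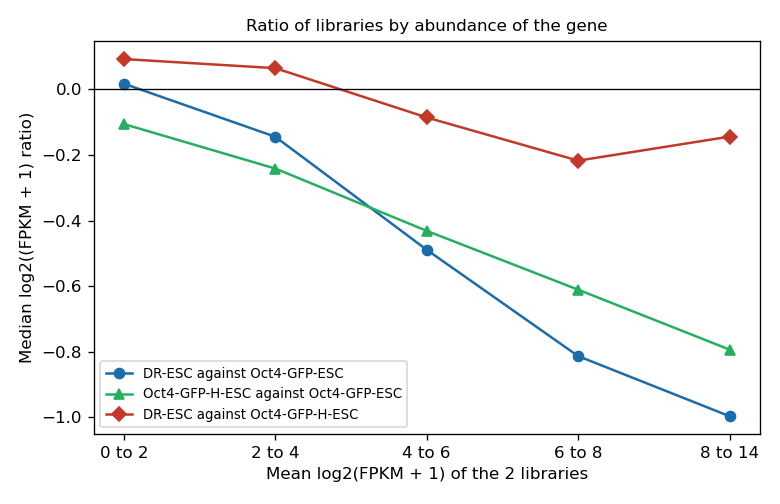
Median log2((FPKM + 1) ratio) of genes (vertical axis) in 5 bins of mean log2(FPKM + 1) of the 2 libraries (horizontal axis), for 3 comparisons, each point the median over all genes of a bin. Both comparisons against Oct4-GFP-ESC fall with abundance, to -0.997 for DR-ESC and -0.79 for Oct4-GFP-H-ESC, while DR-ESC against Oct4-GFP-H-ESC stays between -0.22 and 0.09.

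The pluripotency genes did not move as a block. Pou5f1 (chromosome 17, 35506032 to 35510777 in GRCm38.p6) had 1881 FPKM in Oct4-GFP-ESC, 1037 in Oct4-GFP-H-ESC and 609 in DR-ESC. Its log2 ratio of -1.63 in DR-ESC against Oct4-GFP-ESC became -0.64 with the trend removed. Nanog was near level, with 129, 148 and 145 FPKM, but 1.07 higher on the log2 scale with the trend removed. Sox2 had 232, 147 and 155 FPKM. Klf4 (chromosome 4, 55527137 to 55532475), a factor of the naive state, had 109, 72.6 and 12.3 FPKM, a log2 ratio of -3.04. Esrrb had 149, 97.0 and 62.8 FPKM, a log2 ratio of -1.23 that was -0.42 with the trend removed, and Zfp42 had 48.1, 37.2 and 27.4. In the list of naive and general pluripotency, 12 of 30 genes were lower and 0 higher, at percentile 35.2 of the random lists. Against Oct4-GFP-H-ESC the same list stood apart as lower, with 4 genes lower and 1 higher and a median of -0.62. Klf4, Tbx3, Zfp57 and Tdgf1 led it, Tbx3 and Tdgf1 with 15.4 and 245 FPKM in DR-ESC against 49.1 and 546. Tdgf1, a Nodal co-receptor, was below the 2-fold size (-0.96) with the trend removed.

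Genes of formative and primed pluripotency, the states after the naive one, stood apart as higher. Of 19 genes, 7 were higher and 2 lower against Oct4-GFP-ESC (median 0.56, and 0.87 with the trend removed), and 10 higher and 2 lower against Oct4-GFP-H-ESC (median 1.30). Zic2 had the highest ratio of the list, with 52.7 FPKM in DR-ESC against 10.3 and 4.42. Sox3 had 19.4 FPKM against 4.03 and 5.55, and Fgf5, a marker of the primed epiblast, 5.31 against 1.86 and 0.716. Some leading members were higher still in NPC(GFP-), Sox3 at 96.9, Sfrp2 at 96.3 and Sall2 at 46.3 FPKM. Zic2 and Fgf5 were not, at 8.66 and 0.0764 FPKM. Against NPC(GFP-), 12 of 18 genes of the list were higher in DR-ESC and 4 lower (median 2.13). RNA carried over from NPC(GFP-) was not tested as a source of this list's rise. LIF and STAT3 response genes stood apart as lower, 14 of 20 against Oct4-GFP-ESC (median -1.15) and 8 of 20 against Oct4-GFP-H-ESC (median -0.94). The labels give a LIF dose for both embryonic stem cell libraries but none for DR-ESC, so the doses cannot be compared. Bcl3 had 2.36 FPKM in DR-ESC against 26.5 and 17.5, and Sgk1 21.3 against 125 and 68.8.

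Part of the neural progenitor genes lay between the embryonic stem cells and NPC(GFP-). In DR-ESC 10 of 20 were higher and 2 lower than in Oct4-GFP-ESC (median 0.95), and 11 of 19 higher and 2 lower than in Oct4-GFP-H-ESC (median 1.17). Pax6 (chromosome 2, 105668896 to 105698410), a transcription factor of neural progenitors, had 12.7 FPKM in DR-ESC, 2.34 and 0.540 in Oct4-GFP-ESC and Oct4-GFP-H-ESC, and 52.1 in NPC(GFP-). Irx3 had 17.7 FPKM against 1.82 and 1.36, with 53.9 in NPC(GFP-). Sox1 had 14.4 against 3.73 and 4.11, with 26.6 in NPC(GFP-). Nes, with 7.92 FPKM in DR-ESC against 11.7 and 6.87, stayed under the 2-fold size. Over 38 genes outside this list with at least 20 FPKM in NPC(GFP-) and at most 1 in both embryonic stem cell libraries, the level in DR-ESC stood a median of 2.75% of the way from the higher embryonic stem cell level to that of NPC(GFP-). Hox genes, which pattern the body axis, were higher for 8 of 13 and lower for 2 against Oct4-GFP-ESC (median 1.43), and higher for 9 of 12 and lower for 2 against Oct4-GFP-H-ESC (median 1.75). Hoxa10 had 9.38 FPKM in DR-ESC against 1.11 and 0.629, and Hoxa9 had 4.24 against 0.175 and 0.159. Both genes were low in NPC(GFP-), at 0.277 and 0.0680 FPKM. The list as a whole was also higher in NPC(GFP-) than in Oct4-GFP-ESC, for 9 of 16 genes with 2 lower (median 1.49). That call was lost with no FPKM minimum (percentile 98.97). Against NPC(GFP-), 5 of 17 Hox genes were higher in DR-ESC and 8 lower (median -0.87, percentile 0.42). This lower call was lost with a pseudocount of 5 (percentile 4.65), equal sums (1) and the mean over members (1.48).

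Fibroblast and feeder cell markers gave the lowest list. Of 28 genes, 25 were lower in DR-ESC than in Oct4-GFP-ESC (median -2.51) and 24 lower than in Oct4-GFP-H-ESC (median -2.17), and 0 were higher. The Oct4-GFP-ESC line was grown on fibroblast feeders, and feeder RNA in the embryonic stem cell libraries is not excluded. The values of fibroblast and mesenchymal genes below therefore need not reflect a change in the stem cells themselves. Col1a1 (chromosome 11, 94936224 to 94953042), a chain of type I collagen, had 92.4 FPKM in both embryonic stem cell libraries and 2.03 in DR-ESC. Bgn, a matrix proteoglycan, had 78.1 and 75.2 FPKM against 0.927. S100a4 had 94.7 and 58.1 FPKM and was listed at 0 in DR-ESC. S100a6 had 260.4 and 132 against 2.29, and Emp1 39.7 and 39.9 against 0.303. Of the mesenchymal transition genes, 11 of 20 were lower than in Oct4-GFP-ESC (median -1.28) and 12 of 21 lower than in Oct4-GFP-H-ESC. Without fibroblast markers that list still had 9 of 16 lower (median -1.28). Anxa1 had 0.621 FPKM in DR-ESC against 53.05 and 40.9. Epithelial genes were also lower, 11 of 22 against Oct4-GFP-ESC (median -1.03, and -0.45 with the trend removed) and 7 of 22 against Oct4-GFP-H-ESC (median -0.74). The keratins Krt8 and Krt18 had 27.1 and 25.2 FPKM in DR-ESC against 214 and 134 in Oct4-GFP-ESC. Trophoblast genes, which include both keratins, were lower for 8 of 13 (median -1.19) and for 6 of 14 against Oct4-GFP-H-ESC (median -0.91).

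The TGF-beta lists follow a theme that the series title names, so they are not independent evidence of direction. Of 27 TGF-beta and Nodal ligands, receptors and SMADs, 1 was higher and 8 were lower in DR-ESC than in Oct4-GFP-ESC (median -0.52, percentile 3.98), a median that was 0.23 with equal sums. Against Oct4-GFP-H-ESC 3 were higher and 7 lower (median 0.01, percentile 56.9), a median that was -0.07 with the trend removed. Lefty1 (chromosome 1, 180935022 to 180938401), an inhibitor of Nodal that Nodal signalling induces, had 232 FPKM in DR-ESC against 137 and 87.7. Its log2 ratio to Oct4-GFP-ESC was 0.76, and 1.69 with the trend removed. Lefty2 had 107 FPKM against 173 and 92.4, and Nodal 43.1 against 39.2 and 53.3. Tgfb1 had 0.575 FPKM against 8.67 and 4.28, Tgfbr1 6.25 against 3.08 and 3.67, and Tgfbr2 0.565 against 2.38 and 1.76. Smad7, a target and inhibitor of the pathway, had 17.2 FPKM against 32.6 and 31.9. Of 32 TGF-beta response genes, 2 were higher and 14 lower than in Oct4-GFP-ESC (median -0.67, percentile 0.42), a median that was 0.11 with equal sums. Tnc had 0.541 FPKM against 36.5 and 47.2. The call of this list was lost without its fibroblast markers (27 genes, median -0.55, percentile 9.36) and with the trend removed (median -0.11, percentile 12.6), and also with a pseudocount of 0.1, the median ratio set to 0, upper-quartile scaling and equal sums (percentiles 2.29, 1.32, 1.22 and 1.97). Against Oct4-GFP-H-ESC 12 of 33 were lower and 5 higher (median -0.60), and 7 of 28 lower and 5 higher without the fibroblast markers (median -0.45, below all random lists).

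Germ cell lists share the title's theme and carry the same limit. Of 37 germline, meiosis and piRNA genes, 7 were higher and 2 lower in DR-ESC than in Oct4-GFP-ESC (median 0.52, above all random lists). Dazl (chromosome 17, 50279393 to 50293620), an RNA-binding protein of germ cells, had 8.0 FPKM against 0.712 in Oct4-GFP-ESC and 2.99 in Oct4-GFP-H-ESC. Stra8 (chromosome 6, 34920163 to 34939344), a gene of meiotic entry, had 67.9 FPKM against 23.3 and 11.7, and Sohlh2 17.2 against 3.41 and 5.39. Ddx4 had 13.9 FPKM against 10.2 and 15.5. Against Oct4-GFP-H-ESC 7 of 37 were higher and 0 lower, at percentile 92.3. Genes of primordial germ cell specification stood apart in the latter comparison, where 6 of 17 were higher and 1 lower (median 0.66). Against Oct4-GFP-ESC their median was -0.23 (percentile 96.4), and 0.32 with the trend removed (percentile 99.005). Prdm1 had 5.43 FPKM in DR-ESC against 2.68 and 1.24. Tfap2c had 28.8 against 31.9 and 13.3, Dppa3 23.2 against 27.4 and 10.4, and Prdm14 7.52 against 5.66 and 4.38.

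Of 2 metabolic lists, sterol synthesis had the larger differences. Of 23 sterol synthesis genes, 10 were higher and 0 lower than in Oct4-GFP-ESC (median 0.77, and 1.43 with the trend removed), and 19 higher and 0 lower than in Oct4-GFP-H-ESC (median 1.68). Insig1 (chromosome 5, 28071412 to 28078662), a sterol sensor of the endoplasmic reticulum, had 98.3 FPKM against 30.5 and 14.1. The glycolysis and hypoxia list stood above matched random lists, though most of its 32 genes stayed under the 2-fold size: 4 were higher and 1 lower than in Oct4-GFP-ESC (median 0.15, and 0.70 with the trend removed), and 11 higher and 0 lower than in Oct4-GFP-H-ESC (median 0.53). Aldoc had 26.9 FPKM against 5.83 and 2.52, and Bnip3 50.9 against 12.2 and 5.76.

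Of 16 genes of the 2-cell-like state, a rare embryonic stem cell state that resembles the 2-cell embryo, 14 were higher and 1 lower in DR-ESC than in Oct4-GFP-ESC (median 1.93). The Zscan4 genes are near-identical copies, so the value of each is uncertain: Zscan4c (chromosome 7, 11005745 to 11010547) had 36.4 FPKM against 2.59. DR-ESC and Oct4-GFP-H-ESC did not differ by the 2-fold size in any of the 16 genes (median 0.07). Igfbp5 had 12.9 FPKM in DR-ESC against 0.336 and 0.252. Snhg9 (chromosome 17, 24719531 to 24719965), a short noncoding host gene of a small nucleolar RNA, had 9.37 FPKM and was listed at 0 in the other 3 libraries. Small nucleolar RNA genes had erratic values, and the value of Snhg9 may carry the same limit. Interferon response and antigen presentation genes were lower for 7 of 19 against Oct4-GFP-ESC (median -0.72), with B2m at 16.3 FPKM against 75.3, but not against Oct4-GFP-H-ESC (percentile 12.7). Blood and macrophage markers, of which 5 could be compared, stood apart as lower against both. The DNA methylation and Polycomb list and the p53 list stood above random lists of like abundance with negative medians (-0.18 and -0.16 against Oct4-GFP-ESC) that were positive under each other scaling (0.37 and 0.35 with the trend removed), and both lost that call when lists were not matched on expression (percentiles 79.4 and 80.6) and with the mean over members (98.8 and 82.5).

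**Figure D2:**
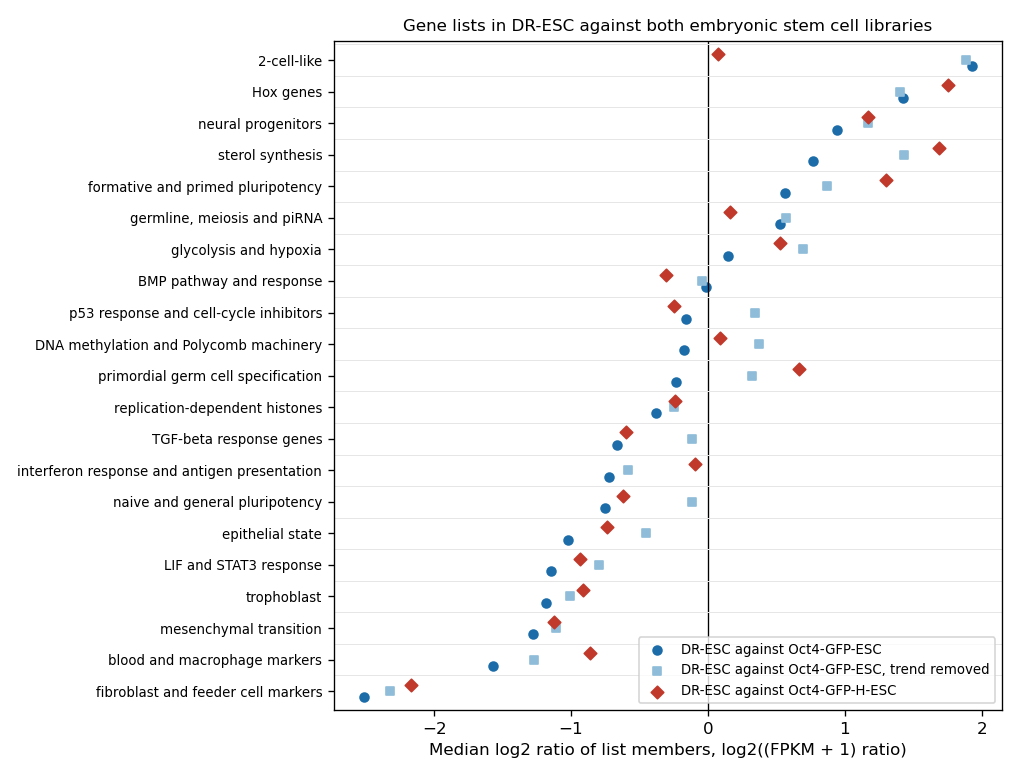
Median log2((FPKM + 1) ratio) of list members (horizontal axis) for the 21 gene lists (vertical axis) that stood apart in DR-ESC against Oct4-GFP-ESC (circles) or against Oct4-GFP-H-ESC (diamonds); squares give the first comparison with the abundance trend removed. Fibroblast and feeder cell markers lie lowest in both (-2.51 and -2.17), and the 2-cell-like list is high (1.93) against Oct4-GFP-ESC only.

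Oct4-GFP-H-ESC against Oct4-GFP-ESC compares the library sorted for a high reporter signal with the unsorted one. The sorted cells had more RNA of 2-cell-like genes, less of the mesoderm gene T and of Fgf8, and similar levels of fibroblast genes. Pou5f1, the gene of the reporter, was not higher, with 1037 FPKM against 1881, a log2 ratio of -0.86, where the most abundant genes had a median of -0.79. Of 12003 genes, 118 were higher and 320 lower (median log2 ratio -0.31). With the trend removed 214 were higher and 67 lower, with the median ratio set to 0 they were 305 and 49 (median of all genes 0.06), and with equal sums 586 and 26 (median 0.26).

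In the 2-cell-like list 13 of 15 genes were higher in the sorted library and 0 lower (median 2.50). Zscan4c had 34.6 FPKM against 2.59 and Sp110 12.3 against 0.778. Among germline, meiosis and piRNA genes 3 of 35 were higher and 2 lower (median 0.43, above all random lists), with Taf7l at 6.54 FPKM against 1.71. T (Brachyury), a gene of the primitive streak, had 0.914 FPKM against 16.1, and Fgf8 0.199 against 8.70. Trh had 41.7 FPKM against 312, and Ifitm1 34.4 against 142. Sterol synthesis genes stood apart as lower, 5 of 23 (median -0.75, and -0.41 with the trend removed), as did neuron genes, 5 of 10 (median -1.005), and ribosomal protein genes, 13 of 97 (median -0.90, and -0.084 with the trend removed). Ribosomal protein genes are abundant and help to set the trend at that end, so its removal cannot tell their difference from the trend. The neuron call was lost with no FPKM minimum (27 genes, median -0.03, percentile 62.1). With the trend removed the named sterol genes Fdps (44.8 FPKM against 129.8) and Fdft1 (19.2 against 44.8) had log2 ratios of -0.94 and -0.74. Fibroblast and feeder cell markers had 1 of 28 genes higher and 0 lower (median -0.07, and 0.15 with the trend removed). Naive pluripotency, TGF-beta response, fibroblast and mesenchymal lists stood above matched random lists with negative medians, between -0.35 and -0.07, that were positive under each other scaling, and with the trend removed this call was lost for the naive (percentile 97.6), fibroblast (97.2) and mesenchymal (96.0) lists. The lower calls of the primordial germ cell, glycolysis and interferon lists were also lost (percentiles 6.71, 6.01 and 1.86), and with a pseudocount of 5 (3, 14.8 and 1.41), and the interferon median (-0.47) was 0.05 with equal sums. The interferon call was also lost with an FPKM minimum of 5 (percentile 4.29) and without matching on expression (7), the naive call without matching (33.3), and the mesenchymal call with each other scaling, an FPKM minimum of 5 and no matching (percentiles from 94.8 to 98.7).

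NPC(GFP-) against Oct4-GFP-ESC compares the neural progenitors with the line they came from. NPC(GFP-) had far less RNA of most pluripotency genes, almost none of some, and high levels of neural progenitor and neuron genes. Pou5f1 had 0.276 FPKM against 1881, Nanog 0.0918 against 129 and Lefty1 0.251 against 137. Other genes were lower but still present. Sox2, which neural progenitors also express, had 103 FPKM against 232, Zfp57 34.3 against 169 and Klf4 7.35 against 109. Of 12848 genes, 2014 were higher and 3292 lower (median log2 ratio -0.25). With the trend removed they were 2367 and 2087, with the median ratio set to 0 3014 and 2209 (median of all genes 0.13), and with equal sums 4893 and 1313 (median 0.63). With Oct4-GFP-H-ESC in place of Oct4-GFP-ESC they were 2386 and 2083.

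All 30 naive and general pluripotency genes were lower in NPC(GFP-) (median -4.72), as were 15 of 18 genes of primordial germ cell specification and 25 of 33 germline genes. Of 33 neural progenitor genes 28 were higher and 1 lower (median 3.42), and of 29 neuron genes 26 were higher and 0 lower (median 2.83). Fabp7, a fatty acid binding protein of neural progenitors, had 168 FPKM against 0.412, Hes5, a Notch target, 67.7 against 0.256, and the long noncoding RNA Miat 241 against 0.966. Among neuron genes Dcx had 34.6 FPKM against 0.0103 and Nefm 178 against 6.98. Imprinted genes were higher for 15 of 34 and lower for 7 (median 0.66), with Nnat at 566 FPKM against 18.4 and Cdkn1c at 224 against 15.01. The basement membrane collagens Col4a1 and Col4a2, counted among endoderm genes, had 857 and 543 FPKM against 59.2 and 40.3. In that list 14 of 28 genes were higher and 6 lower (median 0.99). Sterol synthesis genes were higher for 10 of 23 and lower for 1 (median 0.94). Epithelial genes were lower for 19 of 22 (median -2.25), with Cdh1 at 1.12 FPKM against 83.7. Fibroblast markers were lower for 22 of 28 (median -2.15). Of 19 interferon and antigen presentation genes 14 were lower (median -1.68). Ribosomal protein genes were lower for 86 of 96 (median -1.71, and -0.26 with the trend removed, a trend that they help to set). The mesenchymal list lost its lower call without fibroblast markers (percentile 26.5).

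DR-ESC against NPC(GFP-) compares the GFP-positive with the GFP-negative cells of day 8, the former after further culture. Pluripotency and germ cell genes were higher in DR-ESC, and neural genes lower. Of 12649 genes, 1465 were higher and 1792 lower in DR-ESC (median log2 ratio -0.05). With the sums made equal the median was -0.24 and the counts were 1185 and 2173.

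Of 30 naive and general pluripotency genes 28 were higher in DR-ESC (median 4.07), with Dppa5a at 624 FPKM against 0.246 and Utf1 at 199 against 0.0738. Of 37 germline genes 30 were higher and 1 lower (median 2.22), and of 18 genes of primordial germ cell specification 13 were higher and 1 lower. Dmrt1 had 30.8 FPKM against 0.12 and Mael 22.6 against 0.0787. Of 32 neural progenitor genes 29 were lower and 0 higher (median -2.73), as were 26 of 29 neuron genes (median -3.07), with Nefm at 3.22 FPKM against 178 and Scrt2 at 0.495 against 42.6. Glycolysis and hypoxia genes were higher for 10 of 32 and lower for 1 (median 0.82), with the glucose transporter gene Slc2a3 at 533 FPKM against 55.2. Sterol synthesis genes did not stand apart (median -0.00, percentile 29.0). Fibroblast markers, at low levels in both, did not either (percentile 32.3). The BMP list stood apart as lower, 6 of 18 genes (median -0.67), with Id1, Id2, Id3 and Id4 leading it, but not with the trend removed (percentile 1.86), a pseudocount of 5 (1.53), no FPKM minimum (3.17), upper-quartile scaling (1.01) or equal sums (1.76). Of 28 TGF-beta response genes 13 were higher and 4 lower (median 0.57), led by Lefty1 and Lefty2. This call was lost with an FPKM minimum of 5 (percentile 95.3) and with none (95.7).

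**Figure D3:**
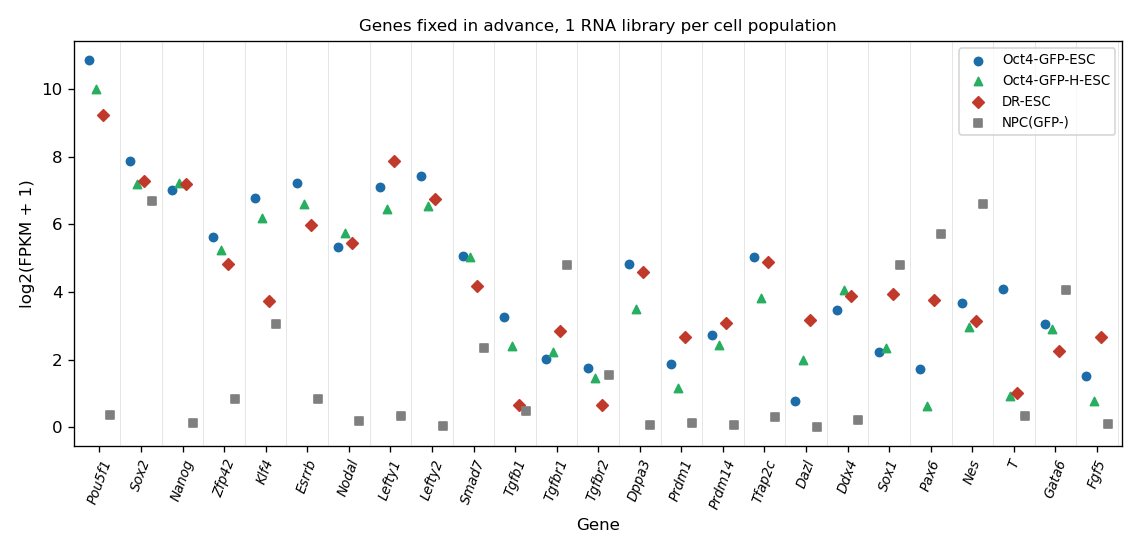
log2(FPKM + 1) of 25 of the 26 genes fixed before the data were examined (horizontal axis), with 1 point per library on the vertical axis and no error bars, since each population has 1 library. Pou5f1 is highest in Oct4-GFP-ESC (1881 FPKM) and near 0 in NPC(GFP-), and DR-ESC hold Pax6 and Sox1 (12.7 and 14.4 FPKM) between the embryonic stem cells and NPC(GFP-).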

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

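The abundance trend, the exchange of Oct4-GFP-ESC for Oct4-GFP-H-ESC and the lists without gene families or, for the mesenchymal list, fibroblast markers were chosen after seeing the data. Of 404 values of named genes, 375 stayed on their side of the 2-fold size with the trend removed, 367 with the median ratio set to 0, 397 with a pseudocount of 0.1 and 366 with 5, and 0 changed sign past it. Most named genes were picked as the highest or lowest genes, or as leading members of lists that stood apart. That choice favours stability, so the shares do not describe all genes. Over all tested genes in DR-ESC against Oct4-GFP-ESC, trend removal moved genes higher from 362 to 578 and genes lower from 1492 to 559. Of 98 list results, 88 kept their call with the trend removed, 95 with the median ratio set to 0, 94 with upper-quartile scaling, 92 with equal sums and 86 with no FPKM minimum, and 0 calls reversed, although the medians of some lists changed sign with scaling, as given beside them in the report. Without replicates these settings measure the processing alone, and unknown depth limits the low genes most. The 98 list results are mostly of lists that already stood apart, so calls gained by other lists are largely not counted.

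Gene counts moved by more than 1.5 times as follows, and the cause was not tested except where the setting itself tests fewer genes or a larger size. In DR-ESC against Oct4-GFP-ESC, genes higher were 61 at 4-fold, 198 with FPKM of at least 5, 730 with a pseudocount of 0.1, 82 with 5, 990 with the median set to 0, 1004 with upper-quartile scaling, 2123 with equal sums and 578 with the trend removed. Genes lower were 156 at 4-fold, 874 with a pseudocount of 5, 489 with the median set to 0, 482 with upper-quartile scaling, 296 with equal sums and 559 with the trend removed. In DR-ESC against Oct4-GFP-H-ESC, genes higher were 54 at 4-fold, 844 with a pseudocount of 0.1 and 142 with 5. Genes lower were 91, 734 and 175, and 314 with FPKM of at least 5. In Oct4-GFP-H-ESC against Oct4-GFP-ESC, genes higher were 37 at 4-fold, 53 with FPKM of at least 5, 241 with a pseudocount of 0.1, 32 with 5, 305 with the median set to 0, 290 with upper-quartile scaling, 586 with equal sums and 214 with the trend removed. Genes lower were 12 at 4-fold, 564 with a pseudocount of 0.1, 121 with 5, 49 with the median set to 0, 53 with upper-quartile scaling, 26 with equal sums and 67 with the trend removed. In NPC(GFP-) against Oct4-GFP-ESC, genes higher were 663 at 4-fold, 911 with a pseudocount of 5 and 4893 with equal sums. Genes lower were 848, 2034 and 1313, with 2087 when the trend was removed and 2083 against Oct4-GFP-H-ESC. In DR-ESC against NPC(GFP-), genes higher were 449 at 4-fold, 925 with FPKM of at least 5 and 624 with a pseudocount of 5, and genes lower 515 at 4-fold and 814 with a pseudocount of 5. The direction of the split between higher and lower genes turned with scaling in the 3 comparisons against Oct4-GFP-ESC and in DR-ESC against Oct4-GFP-H-ESC (489 higher and 444 lower with the median set to 0, 590 and 399 with equal sums), which also turned with a pseudocount of 0.1. In Oct4-GFP-H-ESC against Oct4-GFP-ESC it turned at 4-fold too.

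Lists higher in DR-ESC against NPC(GFP-) were 9 in place of 14 with FPKM of at least 5 and also 9 with no minimum, and lists lower were 5 in place of 8 with a pseudocount of 5. In Oct4-GFP-H-ESC against Oct4-GFP-ESC, lists higher were 5 in place of 8 with the trend removed and lists lower 3 in place of 6 with a pseudocount of 5.

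With a pseudocount of 0.1, Pearson's r across genes was 0.962 between Oct4-GFP-ESC and Oct4-GFP-H-ESC, 0.907 between Oct4-GFP-ESC and DR-ESC, 0.669 between Oct4-GFP-ESC and NPC(GFP-), 0.918 between Oct4-GFP-H-ESC and DR-ESC, 0.649 between Oct4-GFP-H-ESC and NPC(GFP-) and 0.724 between DR-ESC and NPC(GFP-). With FPKM of at least 5 in either library these were, in the same order, 0.962, 0.905, 0.653, 0.917, 0.635 and 0.716, over fewer genes. The order of the 6 pairs did not change.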

Other observations

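The tests of explanations in this part were chosen after the results were seen, as were the genes Etv4 and Etv5 for DR-ESC.

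Several gene groups outside the account above are of interest. Cell-cycle drivers and growth oncogenes did not stand apart in DR-ESC, with 1 of 32 higher and 8 lower than in Oct4-GFP-ESC (percentile 54.6) and 1 higher and 2 lower than in Oct4-GFP-H-ESC (percentile 21.1). BMP response genes held some of the larger differences in DR-ESC against Oct4-GFP-H-ESC, where Id1, a BMP target, had 3.43 FPKM against 36.5, Id3 10.9 against 42.6 and Bmp4 1.41 against 10.4. That list, with 5 of 17 genes lower and 1 higher (median -0.31, percentile 0.47), lost its call under 8 settings, among them an FPKM minimum of 5 (median 0.42). Etv4, a target of FGF signalling, had 16.2 FPKM in DR-ESC against 101 and 92.0 in the embryonic stem cell libraries, while Etv5 had 68.8 against 84.3 and 52.1. Neural crest genes were higher for 7 of 13 and lower for 3 in NPC(GFP-) against Oct4-GFP-ESC (median 1.28), a call lost with no FPKM minimum (percentile 95.3), with Ednrb at 52.1 FPKM against 0.0986. Sst, the somatostatin gene, had 39.8 FPKM in NPC(GFP-), 0.311 in DR-ESC, and was listed at 0 in both embryonic stem cell libraries.

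Fibroblast markers were low in DR-ESC and high in both embryonic stem cell libraries. Removal of the abundance trend left the list at a median of -2.32, which argues against that trend, whatever its source, as the whole cause. Feeder cells in the unsorted library alone would leave the list low after the sort, but its median in Oct4-GFP-H-ESC against Oct4-GFP-ESC was -0.0692. Feeder RNA in both libraries remains open, although a GFP sort would remove feeders unless they were added again, which the labels do not say: over 23 members the SD of the trend-removed log2 ratio between the 2 libraries was 0.53, at percentile 73.4 of matched lists, so 1 fixed feeder profile is neither needed nor excluded. A lower expression of these genes by DR-ESC themselves, from their selection or later culture, was not tested and may also contribute, and this applies to the lower TGF-beta response and mesenchymal lists as well.

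Neural progenitor genes were higher in DR-ESC than in both embryonic stem cell libraries, which carry-over of NPC(GFP-) RNA or spontaneous neural differentiation could explain. For 38 genes outside the list, with at least 20 FPKM in NPC(GFP-) and at most 1 in both embryonic stem cell libraries, the share, which is the excess of DR-ESC over the higher embryonic stem cell level as a percent of the same excess in NPC(GFP-), had a median of 2.75% (bootstrap limits over genes 2.06 and 3.81%). With 2.75% of NPC(GFP-) taken away from DR-ESC, the list's median fell from 0.95 to 0.19 against Oct4-GFP-ESC (percentile 98.28) and from 1.17 to 0.44 against Oct4-GFP-H-ESC (percentile 99.91), and with 3.81% taken away the percentiles were 82.9 and 52.2. For the list as a whole, expression by DR-ESC and a small admixture therefore cannot be told apart. The call turns on the share within its limits, and the 38 genes may themselves be transcribed by DR-ESC, which would raise the share. Of 23 members 11 would need more than 3.81%, among them Sox1 (45.4%), Irx3 (30.4%) and Pax6 (20.7%). Sox1, Irx3 and Pax6 also lay above the 90th percentile of the 38 genes (7.63%). An admixture of 3.81% alone would therefore not give the levels of Sox1, Irx3 and Pax6. Fabp7 and Hes5 would need 2.99 and 2.91%, and Nes was below the higher embryonic stem cell level.

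2-cell-like genes were higher in Oct4-GFP-H-ESC and DR-ESC than in Oct4-GFP-ESC, but not in NPC(GFP-), which was sorted too and had 0.0170 FPKM of Zscan4c against 2.59. The 8 members whose symbols do not begin like that of another member had a median of 1.43 in DR-ESC against Oct4-GFP-ESC, above all random lists. They were chosen by symbol and not by sequence, and may have near-identical copies outside the list. Reads shared between such copies are therefore not excluded as a cause. The abundance trend does not account for the difference, with a median of 1.89 for the whole list after its removal. A larger share of 2-cell-like cells, chance variation between cultures and an effect of the sort on embryonic stem cells stay open and untested, since each population has 1 library.

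A hypothesis that DR-ESC had gained or lost a whole chromosome in most cells was tested by the median trend-removed log2 ratio of each of 20 chromosomes against Oct4-GFP-ESC, for genes with at least 5 FPKM in both. The largest was 0.16, on chromosome 1, and the lowest -0.08, where 3 copies in place of 2 would give 0.58, so no such change was seen, and a change in a minority of cells is not excluded.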
